A study of Mus musculus with 96 samples.

How the data were processed

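Single cells from mouse bone marrow were profiled by RNA sequencing. Per the labels' protocols, marrow of C57BL/6 mice was enriched for CD117 with magnetic beads, stained, and sorted for cells without lineage antigens that carried both Sca-1 and CD117 (LSK cells, the compartment that holds haematopoietic stem cells and multipotent progenitors). Cells were captured on a Fluidigm C1 instrument, cDNA was made with Clontech SMARTer chemistry, and libraries were made with the Nextera XT kit. The 96 samples are 96 cells, numbered in their titles. The titles of 3 of them (cells 25, 56 and 68) mark them as being of poor quality. These 3 were kept apart, and every value is over the other 93 cells unless it says otherwise.

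The authors deposited 1 table of 23955 genes by 96 cells, with log2(TPM + 1) values. TPM is a transcript share scaled so that each cell sums to the same total. The unit was checked on the values: 2 to the power of each value, minus 1, summed to the same total in every column within rounding, and of 304118 recovered values above 0 and under 100 TPM, 100% lay within 0.0005 TPM of a value with 2 decimals. Per the submitters' processing notes, Bowtie2, RSEM and the mm9 build were used; their versions, the gene annotation and any filter on reads or cells are not given in the sources used here. TPM keeps no depth, so the number of reads per cell is unknown and no value carries an interval from read counts. Gene names are those of the table. The annotation at hand was of another build than mm9, so no genome positions are given. It was used to look up 1 paralog pair and 2 pseudogenes by name. The table has no genes with mitochondrial symbols. Of 218 genes in the fixed lists, 4 symbols were not found in the table (Ighm, Ly6g, Siglecf and Adgre1; the older symbol of the last, Emr1, was found).

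TPM was recovered from the deposited log2 values. The plan had been written for TPM values, and this step brought the table to that unit. A gene counted as detected in a cell at 1 TPM or more. Levels are means of log2(TPM + 1), a scale with a pseudocount of 1 that understates differences of low genes. Correlations, variability and clusters used the 10310 genes at 1 TPM or more in at least 5 of the 93 cells. The labels name no animal or culture, so the 93 cells count as 1 sample. No test between groups was therefore possible, and no p-values, standard errors or counts of changed genes were made from cells. Values are given with the SD over cells, and shares of cells with exact Clopper-Pearson 95% intervals, which cover counting error only. A count of 0 of 93 cells allows a share of up to 3.23% by a floor of 3 counts, which is a 1-sided bound; the exact interval, being 2-sided, ends at 3.89%. Correlations across cells describe this 1 sample.

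Before the data were examined, 21 gene lists (10 of them for cell types), 15 gene pairs, the rule for named genes and the alternatives were fixed. The rule names all genes of the sort lists and of the pairs, the 4 members of every other list with the highest mean level together with members found in no cell, the 25 most variable genes, the 10 leading genes of each cluster, and the 10 genes with the highest mean level. For each list with at least 3 members past the filter, the mean pairwise Spearman rho of its members across cells was set among 10000 random lists of the same size, each gene matched on mean level to the 100 nearest genes. A list score is the mean z-score of its members in a cell. Relations between scores (28 among 8 lists, fixed beforehand) are given as rho and Pearson r, with their percentile among 10000 pairs of matched random lists. Another 6 relations, with the immediate early and MHC class II lists, were added after seeing the data. For each gene pair, the number of cells with both genes is set against the number expected from the separate shares, with the SD for random pairing at fixed numbers of cells; this SD was added after seeing the data, also for other levels of detection. Percentiles describe these libraries and are not p-values. Variability is the SD of log2(TPM + 1) over cells minus the running median SD of genes of like mean level. For clusters, the 500 most variable genes, without members of the fixed DNA replication, mitosis and sex-linked lists and without ribosomal protein genes, were scaled and reduced to 10 principal components, and Ward clustering was stopped at the number from 2 to 6 with the highest mean silhouette. No doublet caller was run. Leaving out the cell with over 1.5 times the median number of genes was an alternative.

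The statistics were tested on simulated data made by shuffling each of the 10310 genes over cells. Such shuffling also removes variation that genes share across cells, so the simulated lists, pairs and clusters lack it. Of 200 lists of 12 genes without shared variation, 3.5% fell outside the middle 95% of random lists; with a planted shared factor of 0.4 SD, 100% of 100 lists lay above it. Of 100 unrelated list pairs (15 and 8 genes), 6% fell outside the middle 95%, and of 100 pairs moved in opposite ways by 0.4 SD, 100% lay below it. Of 200 genes given 1.5 times their SD, 84.5% were among the 200 most variable, and 94% at 2 times. In a test with 100 genes raised by 2 SD in 40 cells, 100% of the cells were placed in their planted cluster. With cell numbers shuffled 20 times, the ratio of low values at differences of a multiple of 8 to others lay between 0.945 and 1.05.

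Alternatives fixed beforehand were detection above 0 TPM and at 5 and 10 TPM, all 96 cells, filters on the number of genes per cell, a pseudocount of 0.1, rescaling without ribosomal protein genes, no filter on low genes, partial correlation given the number of genes detected, the squared coefficient of variation, and other numbers of genes, components and methods for clusters. Setting values under 10 TPM to 0 was added after seeing the data, as was the comparison of low values by the difference of cell numbers. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.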

Results

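Transcripts were measured in single LSK cells of mouse bone marrow, the fraction without lineage antigens that carries Sca-1 and CD117 on its surface. The series addresses how blood cell lineages branch from early progenitors, and the data bear on which lineage programs the cells of this compartment hold and how these vary from cell to cell. There were 93 cells without a remark on quality and 3 cells titled as poor. A cell had a median of 3569 genes at 1 TPM or more (quartiles 3268 and 4303, range 2134 to 5415, SD 670). Ribosomal protein genes made up a median of 17.9% of TPM per cell, from 13.7% to 29.8%. The 10 genes with the highest mean level were Eef1a1, Actb, Ubb, Rps18, Rpl32, Rps19, Rpl3, Rps14, Rpl41 and Rpl9, with median levels from 13243 TPM for Eef1a1 to 4850 TPM for Rpl41. All 10 were detected in all 93 cells. No 2 cells held the same values, and the highest correlation between 2 cells was 0.535. The 3 poor-quality cells had 1402 (cell 25), 3499 (cell 56) and 4072 (cell 68) genes detected.

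Transcripts of the antigens that define the sort were found in most but not all cells. Kit, which encodes CD117, was detected in 83 of 93 cells (89.2%, interval 81.1 to 94.7%) at a median of 91.0 TPM over all cells. Ly6a, which encodes Sca-1, was detected in 68 cells (73.1%, 62.9 to 81.8%) at a median of 46.1 TPM, and in 55 cells at 10 TPM or more. Cd34 was found in 92 cells (98.9%, 94.2 to 100.0%) at a median of 564 TPM, and the cytokine receptor Flt3 in 76 cells (81.7%, 72.4 to 89.0%) at a median of 115 TPM. The other stained antigens were rare as transcripts. Fcgr2b was found in 8 cells, Csf1r in 6, Siglec5 in 3 and Fcgr3 in 2, and the eotaxin receptor gene Ccr3 in 0. Among the genes of the lineage antibodies, Cd3e and Cd19 were found in 0 cells, Cd4 in 1 and Cd8a in 4. Itgam, which encodes the myeloid antigen CD11b, was detected in 20 cells (21.5%, 13.7 to 31.2%), and in 14 at 10 TPM or more. Ptprc was found in 85 cells (91.4%), but the gene values do not separate the CD45R isoform that was stained from other CD45 isoforms. These are shares of cells with a transcript, and a cell without one can still carry the protein.

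**Figure D1:**
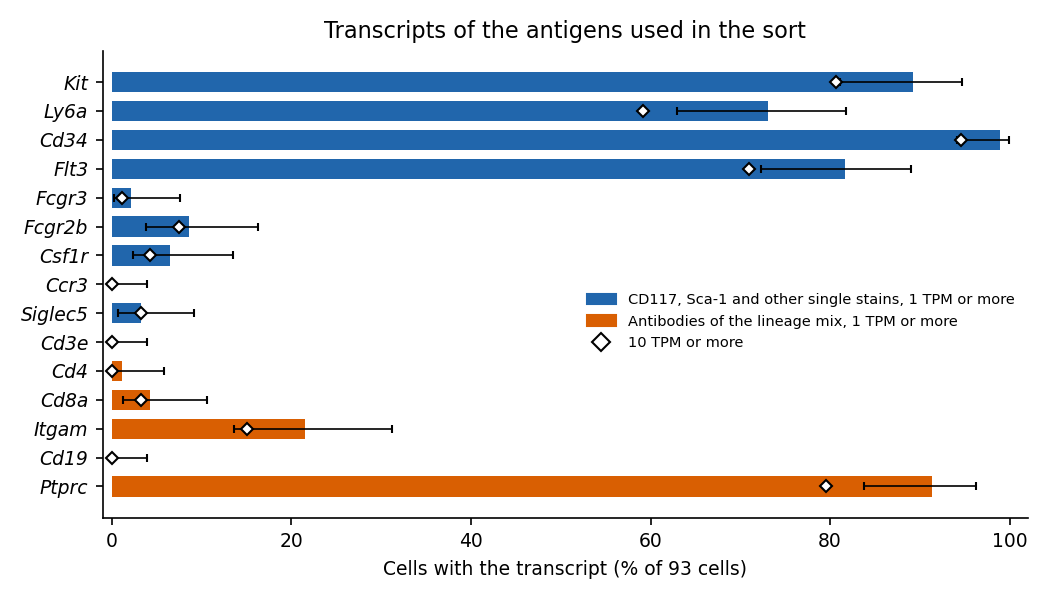
Share of the 93 cells with each antigen's transcript at 1 TPM or more (bars, with exact 95% intervals) and at 10 TPM or more (diamonds). Cd34, Kit, Flt3, Ly6a and Ptprc were each found in over 70% of cells at 1 TPM, and the other genes in at most 21.5%.

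Some genes of the stem cell, early lymphoid and granulocyte lists were widely detected in this sort, while other members of each list were rare. Of the 18 stem cell genes, 5 were detected in at least 50% of cells, and 3 at 10 TPM or more. Ifitm1 (90 cells, mean log2(TPM + 1) 8.28, SD 3.34) and the homeobox gene Meis1 (91 cells, 7.62, SD 2.98) were the highest, followed by the transcription factor gene Hlf (65 cells, 4.39, SD 3.27) and the thrombopoietin receptor gene Mpl (50 cells, 3.99, SD 4.10). Gata2 was found in 56 cells, Mecom in 29, Procr in 23 and Slamf1 in 1. Of 11 early lymphoid genes in the table, 5 were detected in at least 50% of cells, and 2 at 10 TPM or more (Lsp1 and Flt3). The highest were Lsp1 (74 cells, 6.10, SD 3.63), Flt3 (5.91, SD 3.54), Dntt, which encodes the terminal transferase of antigen receptor rearrangement (70 cells, 4.46, SD 4.43), and the L-selectin gene Sell (52 cells, 4.24, SD 4.15). Dntt was at 10 TPM or more in only 38 cells. Other early lymphoid genes were rare, with Il7r in 7 cells, Rag2 in 6, Ccr9 in 3, and Rag1 and Ccr7 in 2 each. Of 15 granulocyte genes, 4 passed 50% of cells, and 2 at 10 TPM or more (Prtn3 and Gstm1). The 4 were Prtn3 (78 cells, 5.65, SD 3.42) and Mpo (59 cells, 4.27, SD 4.33), both of primary granules, Gstm1 (67 cells, 5.19, SD 3.92) and Csf3r (69 cells, 3.51, SD 3.11). Csf3r was at 10 TPM or more in 35 cells. Elane, another primary granule gene, was found in 2 cells, the granulocyte regulator genes Gfi1 and Cebpa in 13 and 9, and Fcnb, Lcn2 and Ltf in 0.

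Markers of the other lineages were mostly rare or not detected. The highest monocyte and dendritic genes were Irf8 (25 cells), Klf4 (12), Ly86 (5) and Csf1r (6), and Ccr2, Cx3cr1, Ly6c2, Batf3 and Zbtb46 were found in 0 cells. Spi1, the gene of the myeloid transcription factor PU.1, was found in 24 cells. The highest megakaryocyte genes were Pf4 (18 cells), Gp9 (13), Itga2b (9) and Selp (7). Vwf was found in 2 cells, and Gp6, Ppbp and Clec1b in 0. Of the 13 erythroid genes, Tfrc, the transferrin receptor gene that many dividing cells use, was found in 30 cells, Gata1 in 3, Hba-a1 in 2 and Ermap in 2, and 7 in none: Klf1, Epor, Car1, Gypa, Aqp1, Slc4a1 and Sphk1. Among mast cell, basophil and eosinophil genes only Mcpt8 (10 cells) and Cpa3 (4) were detected, and Gzmb, Ms4a2, Fcer1a, Prss34, Cma1, Tpsb2, Epx and Prg2 were not. In the B cell list, Cd79b, a part of the B cell receptor complex, was found in 47 cells (mean 2.82, SD 3.57), but Blnk in 8, Vpreb1 in 2, Ebf1 in 1, and Cd19, Ms4a1, Pax5 and Igll1 in 0. In the T and NK cell list, Nkg7, a gene of cytotoxic granules, was found in 77 cells (mean 6.71, SD 3.95) and the kinase gene Lck in 35 (2.38, SD 3.31), against 6 for Cd3d, 4 for Cd8a and 0 for Cd3e, Cd3g and Ncr1. In the stroma and endothelium list, Lepr was found in 71 cells at a median of 2.33 TPM, but at 10 TPM or more in only 6. Pdgfrb was found in 20, Kdr in 3, Bglap in 2, and Cxcl12, Col1a1 and Cdh5 in 0.

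**Figure D2:**
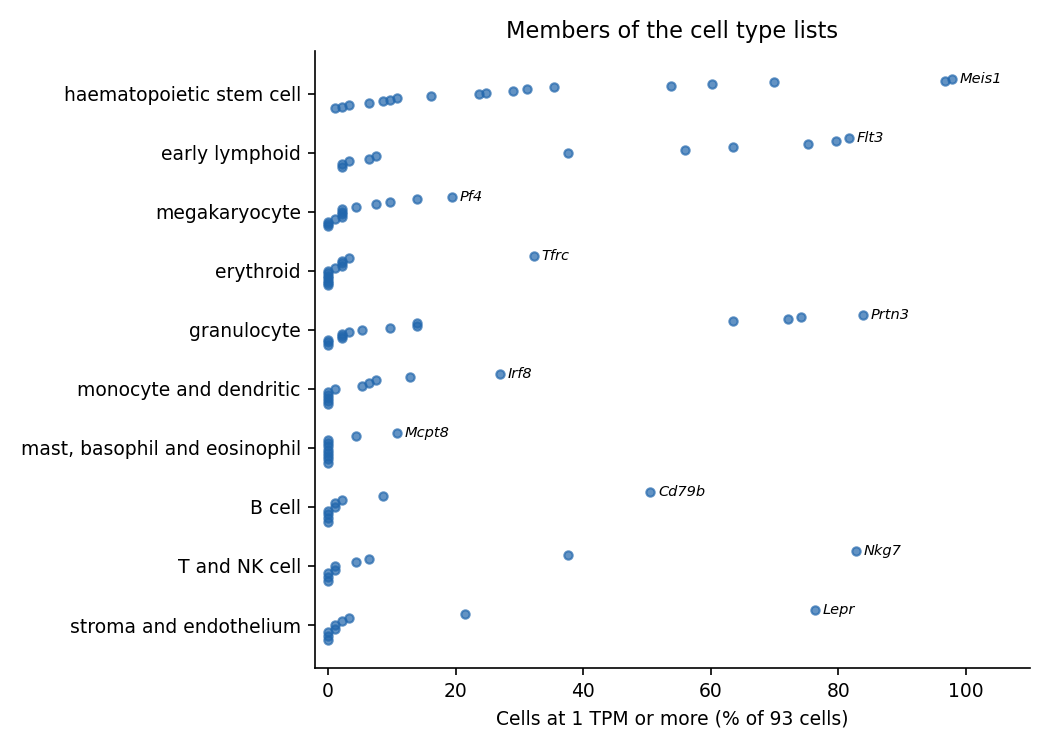
Each point is 1 gene of a cell type list, placed at the share of the 93 cells with 1 TPM or more, and the most widely detected gene of each list is named. Stem cell, early lymphoid and granulocyte lists have 5, 5 and 4 members in at least 50% of cells (3, 2 and 2 at 10 TPM or more), and the other lists have at most 1.

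Genes of the immediate early response, which follow growth factor and stress signals, differed in how widely they were detected. Of 15 immediate early and heat shock genes, 7 were found in at least 50% of cells, and the median share was 46.2%. The 4 highest varied widely. Fos was found in 86 cells (mean 7.28, SD 3.99), Egr1 in 89 (6.89, SD 4.30), Zfp36 in 81 (6.58, SD 3.66) and Dusp1 in 82 (6.50, SD 3.52). Egr2 was found in 4 cells and Atf3 in 2. The heat shock genes Hspa1a and Hspa1b were each found in 1 cell. Interferon response genes were found in fewer cells, with Stat1 in 43, Oasl2 in 35, Usp18 in 32 and Bst2 in 29. The MHC class II genes were found in a minority, H2-Ab1 in 27, Cd74 in 24, H2-Aa in 13 and H2-Eb1 in 7. Of the Hox genes and their partners, Meis1 was followed by Hoxa9 (60 cells, 3.36, SD 2.91), Pbx1 (47 cells) and Hoxa7 (30 cells). Of the cyclin-dependent kinase inhibitors, Cdkn1b, which encodes p27, was found in 82 cells (4.00, SD 2.08), Cdkn1a in 24, Cdkn1c in 11 and Cdkn2c in 10. Among housekeeping genes, Eef1a1 (13.64, SD 0.56), Actb (13.44, SD 0.46), B2m (12.26, SD 0.63) and Gapdh (10.38, SD 1.57) were found in all 93 cells.

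Members of several lists varied together across cells. The mean pairwise rho was 0.404 over the 20 mitosis genes, 0.326 over the 16 DNA replication genes, 0.303 over the 4 MHC class II genes, 0.242 over 11 immediate early genes, 0.202 over 8 early lymphoid genes and 0.128 over 15 stem cell genes. All of these were above every one of the 10000 matched random lists, whose medians lay between 0.015 and 0.026. The monocyte and dendritic list (0.131, percentile 99.8), the interferon list (0.101, percentile 99.9) and the granulocyte list (0.072, percentile 98.1) were also high. The megakaryocyte (0.077, percentile 92.4), Hox (0.029, percentile 71.7), T and NK cell (−0.036, percentile 21.9), cyclin-dependent kinase inhibitor (−0.017, percentile 21.3), sex-linked (0.031, percentile 55.9) and stained antigen lists (0.004, percentile 40.9) lay among random lists. The 6 housekeeping genes lay at the low end (−0.067, percentile 0.29). The erythroid, B cell, stroma, lineage antibody, and mast cell, basophil and eosinophil lists had fewer than 3 members past the filter. Over the alternatives, the granulocyte list lay above the middle 95% of random lists in 3 of 6 (lowest percentile 90.9), and the monocyte and dendritic list in 4 of 5 (lowest 87.0, with a rho of 0.032, without the filter on low genes). The megakaryocyte list lay above it in 1 of 6.

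Cells high in stem cell genes were low in early lymphoid genes. The scores of the 2 lists had a rho of −0.637 across the 93 cells, below all 10000 pairs of matched random lists, whose median was 0.202. Pearson r was −0.599, and −0.624 without the 2 cells farthest from the median of the stem cell score. The opposition was spread over both lists. All 15 stem cell genes past the filter had a negative rho with the early lymphoid score, from −0.454 for Gata2, −0.435 for Ifitm1 and −0.385 for Mpl to −0.054 for Ctnnal1. All 8 early lymphoid genes had a negative rho with the stem cell score, led by Dntt (−0.560), the chromatin organiser gene Satb1 (−0.527) and Notch1 (−0.376). These genes were named for their rho, after it was seen. The stem cell score also ran against the monocyte and dendritic score (rho −0.359, r −0.324, below all random pairs), and the early lymphoid score ran with it (rho 0.378, r 0.536, percentile 99.7). The r of 0.536 fell to 0.418 without the 2 cells farthest from the median of the early lymphoid score. Cell 73, which had the highest monocyte and dendritic score (3.46), was not among those left out. The monocyte and dendritic score rests on 5 genes absent from most cells (Irf8 in 25, Klf4 in 12, Siglech in 7, Csf1r in 6, Ly86 in 5). With values under 10 TPM set to 0, too few of them passed the filter to compute these relations. The early lymphoid score ran against the megakaryocyte score (rho −0.213, r −0.247, percentile 0.34, and 1.87 given the number of genes detected). The megakaryocyte score likewise rests on 4 genes absent from most cells (Pf4 in 18, Gp9 in 13, Itga2b in 9, Selp in 7). The stem cell and megakaryocyte scores had a rho of 0.231 (r 0.216, percentile 90.6), and the stem cell and granulocyte scores one of −0.086 (r −0.151, percentile 0.93). Given the number of genes detected, the last 2 lay at percentiles 98.1 and 12.1. Of the 28 relations, 8 lay below the lowest 2.5% of random pairs and 1 above the highest, where 1.4 in all would lie outside by chance. Given the number of genes detected, 3 lay below and 2 above.

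**Figure D3:**
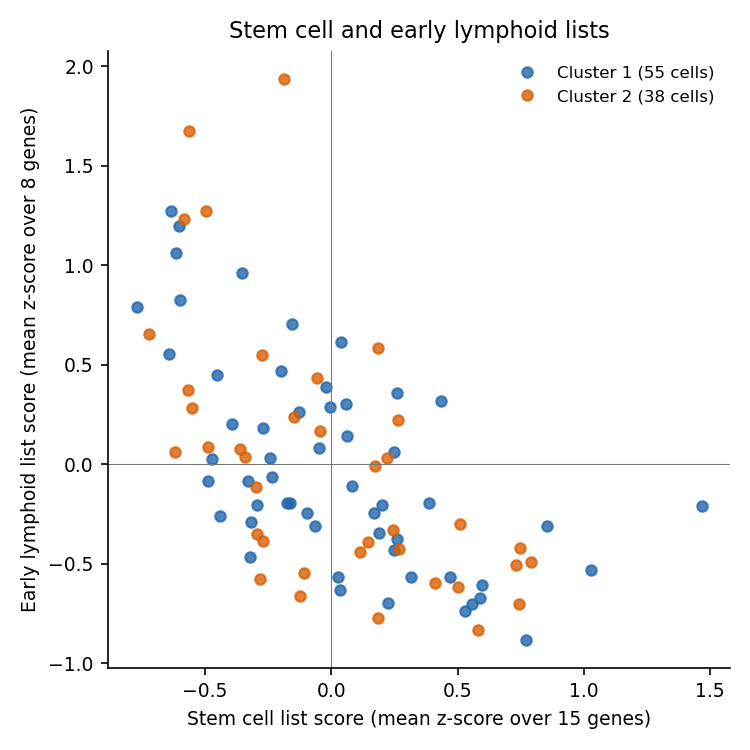
Early lymphoid against stem cell list score (mean z-scores over 8 and 15 genes) in the 93 cells, 1 point per cell, coloured by cluster. The points run from upper left to lower right (rho −0.637), and cells of both clusters lie along most of the run. The cell with the highest stem cell score (1.47) belongs to cluster 1. The cell with the highest early lymphoid score (1.94) belongs to cluster 2.

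At 1 TPM, Dntt and Procr lay farthest below the number of shared cells that separate shares predict among the 15 pairs of regulators and markers, but which pair did so depended on the level counted as detected. Dntt was found with Procr, a stem cell surface receptor gene, in 12 cells against 17.3 expected (−2.94 SD from it), where the SD is that of random pairing with the same number of cells for each gene. It was found with Mecom in 18 against 21.8 (−1.98 SD) and with Pf4 in 13 against 13.5. Kit and Ly6a were both detected in 63 cells against 60.7 expected, Gata2 and Spi1 in 16 against 14.5, Gata2 and Cebpa in 6 against 5.42, Cebpa and Spi1 in 4 against 2.32, Dntt and Mpo in 45 against 44.4, and Gata1 and Spi1 in 1 against 0.774. Gfi1 and Irf8, regulators of granulocyte and monocyte fates, were found together in 2 cells against 3.49 expected. Flt3 was found with Procr in 18 against 18.8, with Mecom in 22 against 23.7, with Vwf in 1 against 1.63 and with Slamf1 in 0 against 0.817. Pf4 and Mpo were both found in 10 cells against 11.4. The counts of Slamf1 (1 cell) and Vwf (2 cells) are too low to tell, and Kit and Ly6a could overlap only in 58 to 68 cells. Of the 15 counts, 9 moved by over 1.5 times with any value above 0, 10 at 5 TPM and 11 at 10 TPM. At 5 TPM, the pairs farthest below expectation were Mecom and Flt3 (10 cells against 14.6, −2.62 SD), Mecom and Dntt (4 against 8.60, −2.33 SD) and Pf4 and Mpo (2 against 5.73, −2.24 SD), followed by Procr and Dntt (3 against 6.45, −1.95 SD). At 10 TPM, Dntt was found with Procr in 3 cells against 5.72 expected (−1.60 SD), with Mecom in 4 against 7.76 (−1.96 SD), with Mpo in 19 against 16.3 and with Pf4 in 2 against 4.09. Flt3 was then found with Mecom in 9 against 13.5 (−2.53 SD), with Procr in 9 against 9.94 and with Vwf in 0 against 0.710. Pf4 and Mpo were then found together in 2 against 4.30, Gata2 and Spi1 in 9 against 7.74, Gfi1 and Irf8 in 1 against 2.37, and Gata1 and Spi1 in 0 against 0.516. With any value above 0, Dntt and Procr were found together in 19 against 24.1 (−3.30 SD).

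More cells held DNA replication genes than mitosis genes, and both shares depended on the level counted as detected. At least 50% of the 16 replication genes were detected in 63 of 93 cells (67.7%, 57.3 to 77.1%). Pcna (80 cells, 6.13, SD 3.61), the sliding clamp of DNA polymerase, and the helicase subunit genes Mcm6 (81 cells, 5.78, SD 3.68), Mcm3 (75 cells, 5.61, SD 3.66) and Mcm7 (71 cells, 5.39, SD 3.92) were the highest. At least 50% of the 20 mitosis genes were detected in 18 cells (19.4%, 11.9 to 28.9%), of which 17 also passed for replication. Top2a (46 cells, 3.43, SD 3.77), Birc5 (42 cells, 2.29, SD 3.15), Kif23 (32 cells, 2.15, SD 3.17) and Mki67 (35 cells, 2.14, SD 3.07) were the highest. Birc5 was at 10 TPM or more in 19 cells. The lines run through a continuous range, and 23 cells lay within 1 gene of the line for replication and 5 for mitosis. With 25% of the members as the line, the mitosis share was 44.1%. With any value above 0 counted, the replication and mitosis shares were 98.9% and 48.4%, and at 10 TPM they were 48.4% and 14.0%. The 2 scores had a rho of 0.428 (r 0.159, percentile 93.6), and of 0.064 given the number of genes detected, with which the scores had a rho of 0.628 and 0.620.

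The most variable genes were of several kinds. Car2, a carbonic anhydrase gene (91 cells, SD 3.14), Egr1 (SD 4.30), Fos (SD 3.99), Plac8 (92 cells, SD 2.88), Dntt (SD 4.43), the chemokine gene Ccl4 (69 cells, SD 4.40), Nkg7 (SD 3.95), Ifitm3 (90 cells, SD 2.69), Lgals9 (87 cells, SD 3.59), Dhrs3 (70 cells, SD 4.45), Golt1b (69 cells, SD 4.25), Kars (85 cells, SD 4.04), Plp2 (73 cells, SD 4.08), Cox6a1 (89 cells, SD 2.96), Eno1 (80 cells, SD 3.79) and Ubc, Sept2, Stmn1, Tuba1b, H2afz and Hmgn2 (92 or 93 cells, SD 1.93 to 3.38) were among the 25. Rps27 (SD 4.46) and its paralog Rps27rt (SD 3.65) led the ranking, but the log2 of their summed TPM had an SD of only 0.51, so the split of reads between these near-identical genes is uncertain. Gm15772 and Gm13363 are annotated as pseudogenes, and their values may likewise hold reads of other genes. Ranked by the squared coefficient of variation on TPM, which favours rarely detected genes, 2 of the 25 were kept.

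Clustering without the members of the fixed replication and mitosis lists gave 2 clusters that differed in replication, mitosis and immediate early genes. The mean silhouette was highest for 2 clusters (0.165, against at most 0.102 in 20 shuffled data sets). Each gene was shuffled on its own, which also removes shared variation such as that with the number of genes detected. This reference therefore cannot tell 2 groups from a cut through a gradient. Cluster 1 held 55 cells (59.1%, 48.5 to 69.2%). Its leading genes, ranked by difference from the other cells, were Egr1, Ccl3, Zfp36, Btg2, Ccl4, Fos, Tcp11l2, Ier2, Shisa5 and Sepp1. Cluster 2 held 38 cells (40.9%, 30.8 to 51.5%). Its leading genes were Top2a, Prim1, Mrpl18, Dctpp1, Cks1b, Tipin, Rfc4, Rhno1, Gcsh and Cbx5, of which Top2a, Prim1, Rfc4 and Tipin are genes of DNA replication and chromosome handling. Of the leading genes, Ier2, Top2a, Mrpl18, Rfc4, Gcsh and Cbx5 had not entered the clustering. Other cell cycle genes, such as Prim1, Tipin and Cks1b, did enter the clustering. All 16 replication and all 20 mitosis genes of the lists, which had been left out of it, were higher in cluster 2 (median difference of log2(TPM + 1) 2.70 and 2.17). All 7 immediate early genes that had not entered it were lower in cluster 2 (median difference −1.16), and 6 of 8 Hox genes and partners were lower (median −0.51). These medians lay outside all random lists matched on level. Fos, Egr1, Ier3 and Zfp36 of the immediate early list had entered the clustering. Members of that list varied together, so the 7 left out are not independent of it. Stem cell genes (8 of 15 higher in cluster 2, median difference 0.04) and early lymphoid genes (4 of 8 higher, median 0.03) differed little, but lay low among matched random lists, whose medians were 0.42 and 0.62 (percentiles 2.09 and 3.22). Neither cluster was led by the markers of a cell type list, and neither was named. The median number of genes detected was 3323 in cluster 1 and 4402 in cluster 2, and the first principal component (7.56% of the variance) had a rho of 0.867 with it. The second component (3.20%) had a rho of −0.781 with the stem cell score and of 0.759 with the early lymphoid score, and of −0.027 with the number of genes detected. Mpl, Ifitm1, Dntt, Lsp1 and Sell of these lists had entered the components, so its relations with the 2 scores are partly built in. With 1000 variable genes the largest cluster held 76.3% of the cells.

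**Figure D4:**
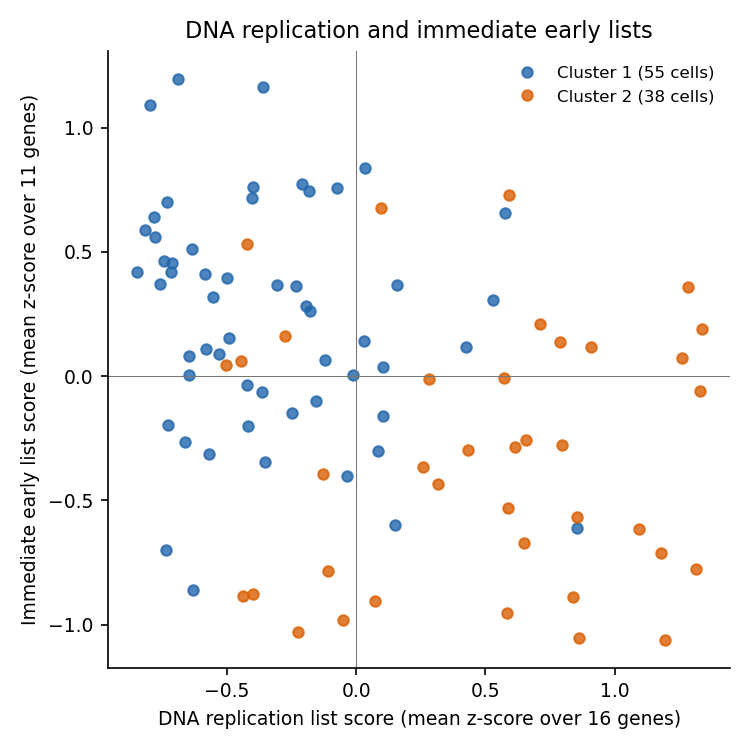
Immediate early against DNA replication list score (mean z-scores over 11 and 16 genes) in the 93 cells, 1 point per cell, coloured by cluster. Cells with high replication scores tend to have low immediate early scores (rho −0.396), and most of them belong to cluster 2.

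Y-linked genes were found in nearly all cells. At least 1 of 4 such genes was detected in 83 of 93 cells (89.2%, 81.1 to 94.7%): Ddx3y in 65, Uty in 37, Eif2s3y in 36 and Kdm5d in 19. Xist, the RNA of the inactive X chromosome, was detected in 1 cell, at 7.45 TPM, which also held a Y-linked transcript. Neither was found in 10 cells.

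Low values near the detection line recurred at a regular spacing of the cell numbers. For the 1814 genes at 200 TPM or more in exactly 1 of the 96 cells, a value above 0 and up to 5 TPM was found in 18.1% of the cells whose number differed from that cell's by a multiple of 8, and in 8.69% of the other cells. The ratio of the 2 shares was 2.76 for values up to 0.5 TPM, 1.26 for values from 2 to 5 TPM, 1.08 from 5 to 10 TPM and 0.997 from 10 to 50 TPM. Of all values counted as detected at 1 TPM, 27.2% were below 10 TPM. Among genes counted above in at least 10 cells, some were at 10 TPM or more in fewer cells by over 1.5 times: Ccl4 in 40, Dhrs3 in 44, Pbx1 in 30, Mecom in 19, Hoxa7 in 18, Procr and H2-Ab1 in 14, Cd74 and Uty in 13, Pf4 and Pdgfrb in 10, H2-Aa in 8, Gp9 in 7, and Cdkn2c and Mcpt8 in 5.

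**Figure D5:**
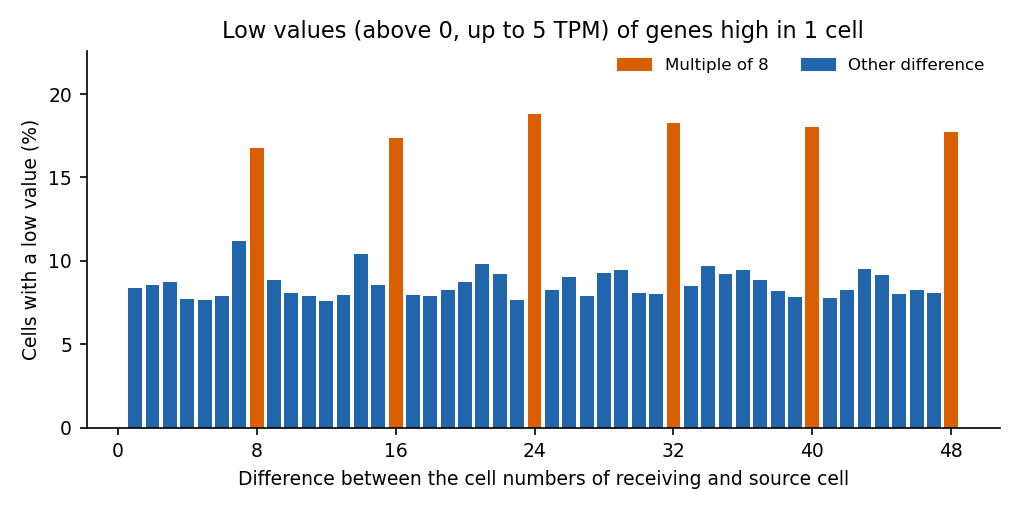
Share of cells with a value above 0 and up to 5 TPM, for the 1814 genes high in exactly 1 cell, by the difference between that cell's number and theirs (bars; orange for multiples of 8). The share was 16.8% at a difference of 8 and 18.8% at 24, against 8.36% at 1 and 11.2% at 7.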

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

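The 3 cells titled as poor in quality entered only the comparison of low values by cell number and the alternative with all 96 cells, and 2 of them held values above all 93 other cells. Ribosomal protein genes made up 41.3% of TPM in cell 56 and 36.3% in cell 68, where the highest of the 93 cells had 29.8%. The 10 highest genes took 15.3% of TPM in cell 56 and 13.1% in cell 68, where the highest of the 93 had 11.6%. In both cells the number of genes detected (3499 and 4072) lay inside the range of the 93. Cell 25 had 1402 genes, fewer than any other cell, with a ribosomal protein share of 20.1%.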

How the results depend on the processing

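Of 160 recomputations of the main values under 17 alternatives, 126 stayed within their limit and 34 moved beyond it. Of 470 recomputations of other values, 424 stayed and 46 moved. The limit was the exact interval for a share and a factor of 1.5 for a count. For other values it was the SD over cells, over list members or over random lists. Only correlations can change sign, and they are a part of these recomputations. Among correlations, 0 of the main values and 11 of the other values changed sign. Of these 11, 8 were relations between list scores, 4 of them given the number of genes detected: granulocyte and DNA replication (0.123 to −0.074), granulocyte and mitosis (0.134 to −0.055), T and NK cell and mitosis (0.111 to −0.064), and megakaryocyte and mitosis (0.047 to −0.111). None of the 11 lay outside the middle 95% of random lists as reported. The stem cell and early lymphoid rho stayed between −0.650 and −0.626 in all 7 alternatives run for it and below the random pairs in all 7. Leaving out cells under 50% of the median number of genes removed 0 cells and so tested nothing. The filter at 1.5 times the median removed 1 cell, so its values, which are counted above, could move only little. For k-means the number of clusters was set to that of the main result, so this count stayed by construction. The cause of the shifts below was not tested, except that another line of detection or membership counts other values by construction. Setting values under 10 TPM to 0 was chosen after seeing the data. The number of reads per cell is unknown, so missing transcripts cannot be parted from unsequenced ones.

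With any value above 0 as detected, the median number of genes was 4555, and Kit and Flt3 were each found in 98.9% of cells. The replication share was then 98.9%, the mitosis share 48.4%, cells with a Y-linked gene 96.8% and with Xist 6.45%. The highest Xist value was 7.45 TPM, and the next was 0.09 TPM. At 5 TPM the median was 2838 genes, Ly6a was found in 60.2%, the replication share was 51.6% and a Y-linked gene was found in 79.6%. At 10 TPM the median was 2589 genes, Kit was found in 80.6%, Ly6a in 59.1%, Flt3 in 71.0%, a Y-linked gene in 78.5% and Xist in 0%, and the replication share was 48.4%. With 25% of members as the line, the mitosis share was 44.1% and the replication share 96.8%.

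A pseudocount of 0.1 kept 16 of the 25 variable genes and put 73.1% of cells in the larger cluster; the squared coefficient of variation kept 2 of 25. The larger cluster held 77.4% without the filter on low genes and 76.3% with 1000 variable genes. Without the filter, the mean pairwise rho was 0.089 for stem cell, 0.136 for early lymphoid, 0.038 for granulocyte and 0.139 for immediate early genes. With values under 10 TPM set to 0 it was 0.146 for stem cell, 0.249 for early lymphoid, 0.556 for mitosis and 0.216 for immediate early genes. Given the number of genes detected, the replication and mitosis rho was 0.064.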

Other observations

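The relations with the immediate early and MHC class II lists and the genes outside the lists were chosen only after the results had been seen. So were the tests by values of 10 to 50 TPM, by B and T cell markers and by heat shock genes. Partial correlation given the number of genes detected was an alternative fixed beforehand. Its use as a test of an explanation was set only after the results had been seen. The opposition of stem cell and early lymphoid genes reached genes outside every fixed list. Of 10176 such genes, 8 had a lower rho with the difference of the 2 scores (stem cell minus early lymphoid) than any gene had with the difference of any of 200 pairs of random lists (lowest −0.481). They were H2afy (−0.676), which encodes the histone variant macroH2A, Gpr97 (−0.635), Il12a (−0.603), a subunit gene of interleukin 12, Plac8 (−0.588), Ncf1 (−0.528), a gene of the phagocyte oxidase, Tmsb10 (−0.519), Cd52 (−0.503) and Mn1 (−0.484). All 8 had a positive rho with the early lymphoid score (0.472 for Tmsb10 to 0.575 for Gpr97) and a negative rho with the stem cell score (−0.378 for Mn1 to −0.686 for H2afy). On the stem cell side, Tgfbr3 (0.488), Car2 (0.484), Grb10 (0.450) and Socs2 (0.442) came first, but none lay above the highest random value of 0.508. These genes were picked by their values.

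The immediate early and DNA replication lists ran opposite ways across cells, with a rho of −0.396 (r −0.376), below all 10000 matched random pairs (median 0.284). Without the 2 cells farthest from the median of the immediate early score, r was −0.334. All 16 replication genes had a negative rho with the immediate early score, and all 11 immediate early genes with the replication score, led by Egr1 (−0.369) and Zfp36 (−0.348). The immediate early score had a rho of −0.202 with the mitosis score (percentile 0.01) and of −0.068 with the stem cell score (percentile 0.35); given the number of genes detected, these were −0.056 and −0.048 and lay among random pairs (percentiles 27.9 and 27.7). With the early lymphoid score its rho was 0.072 (percentile 11.9). For MHC class II genes the rho was −0.066 with the early lymphoid score and 0.123 with the stem cell score, both among random pairs.

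Reads crossing between libraries whose numbers lie 8 apart are a candidate explanation of the low values that recur at that spacing. The excess of low values in such cells, over other cells, was 1.85 times as large for the genes with the highest source levels (median 592 TPM) as for those with the lowest (median 228 TPM; bootstrap interval of the ratio 1.56 to 2.25). Depth that differs between cells cannot account for it, since 95 of the 96 receiving cells had the higher share from numbers a multiple of 8 away. Likeness of cells 8 apart would carry values of 10 to 50 TPM too, but the ratio for these was 0.997. Sharing at 200 TPM or more could not show, since the genes were chosen for reaching it in exactly 1 cell. Over all genes past the filter, the mean correlation between 2 cells was 0.401 for numbers a multiple of 8 apart and 0.395 for others. With values under 10 TPM set to 0, it was 0.356 and 0.354. Where on the instrument or among the indexes the numbers lie was not given in the sources used here.

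The opposition of the stem cell and early lymphoid lists was not removed by any of 3 technical explanations tested. Given the number of genes detected, rho was −0.638. With values under 10 TPM set to 0, it was −0.645 (random pairs not below −0.269). This takes out the levels at which low values recurred for genes high in exactly 1 cell, and genes high in several cells were not examined. Mature B or T cells, which the lineage antibodies should have removed, would bring Cd19, Ms4a1, Cd79a, Cd3e or Cd3g, but only 1 cell held any of them at 10 TPM or more (Cd79a), and without it rho was −0.646. Leaving out 1 cell can move rho only little, so what bears on this explanation is the scarcity of the markers. No biological explanation was tested, since the labels give no group for it.

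The opposition of immediate early and DNA replication genes also outlasted 2 technical tests. Given the number of genes detected, rho was −0.311 (percentile 0.07 of random pairs), and with values under 10 TPM set to 0, against reads crossing between libraries, it was −0.385. The limit given above for the cut at 10 TPM applies here too. A response to tissue handling before lysis could still play a part. Hspa1a or Hspa1b was found in only 1 cell, but the labels give no time from harvest to lysis, so tissue handling before lysis and a state of the cells in the marrow cannot be told apart. No biological explanation was tested.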
